A study of Arabidopsis thaliana with 6 samples.

How the data were processed

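Gene expression was measured in mature rosette leaves of Arabidopsis thaliana, wild type (WT) and the mlo2 mlo6 mlo12 triple mutant, collected 5, 6 and 7 weeks after sowing under normal growth conditions. MLO genes encode membrane proteins whose loss makes leaves resistant to powdery mildew fungi. Each combination of genotype and age was represented by 1 Affymetrix array, which gave 6 arrays, 3 per genotype. Per the labels, total RNA was extracted with Trizol and biotin-labelled cRNA was prepared and fragmented by the manufacturer's protocol. Nothing in the labels says how many plants went into an array, or that arrays came from separately grown cultures, so the p-values measure the spread between these 6 arrays only, which includes any dependence of the genotype difference on age.

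The values used were the deposited log2 values of each probe set, which the authors made with RMA (background correction, quantile normalization and 1 summary value per probe set), per the submitters' processing notes. The RMA version and the annotation used were not given in the sources used here. The log2 scale was read from the values, which ran from 1.72 to 13.4 over the 6 arrays with array medians between 3.81 and 3.88. The values were not centred per gene. Scanner intensities were not used here. RMA makes the distributions of the arrays alike, so a change in the total amount of mRNA per leaf cannot be seen, and values of dim probe sets are compressed towards the background. The number of arrays limits the precision.

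The table held 22810 probe sets. The 64 control probe sets of the array were set aside, and 22746 were tested. The platform annotation paired 13513 of them with 1 gene (59.4%), covering 13356 genes, and 503 with several genes. The other 8730 were not listed in it and are unnamed here, which does not mean that they have no gene. Names were looked up by gene identifier in a RefSeq table of the TAIR10.1 assembly, where 13436 of the 13513 had an entry and 0 symbols changed. No probe set with several genes was named.

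Tests were run with limma 3.58.1 in R 4.3.3. The genotype effect (mutant minus WT, averaged over ages) and the age effect (7 minus 5 weeks, averaged over genotypes) came from a linear model with genotype and age as a factor of 3 levels, which left 2 residual degrees of freedom. The genotype-by-age interaction was the change of the mutant minus WT difference over the 2 weeks between the first and last harvest, from a model with age as a number. It also left 2 residual degrees of freedom, and changes at 6 weeks shared by both genotypes, which do not follow a straight line over age, went into its error. A model with age as a factor (1 residual degree of freedom) was added as an alternative after the data had been seen. P-values were moderated with eBayes and adjusted over the 22746 probe sets by the Benjamini-Hochberg method, with a threshold of 0.05. Genotype differences at a single age rest on 1 array per side and were counted at an absolute log2 difference of at least 1, without a test.

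Gene lists were tested with camera of limma at a preset inter-gene correlation of 0.01, on 1 probe set per gene (that of the highest mean), for lists with at least 4 measured genes. Fry and an estimated inter-gene correlation were alternatives. With an estimated correlation, camera uses the 2 residual degrees of freedom in place of those from the number of genes. At single ages, the median difference of a list was placed among 10000 random lists of equal size, matched on mean expression in 20 bins. Before the data were examined, 25 lists with 345 entries were written down. Of these entries 40 were measured on a probe set with 1 gene, and only 3 lists reached 4 measured genes. A further 20 lists were therefore formed from the gene symbols that the annotation does hold, such as plastid-encoded genes and named defence genes. They were formed after the correlations of the arrays and their control probe sets had been seen, and before any gene was fitted. They are called added lists. The 3 lists and the 20 added lists were adjusted separately, a choice made after an adjustment over all lists together had been seen; that joint adjustment is among the alternatives.

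The rule for named genes was written before the data were examined: the targeted genes; up to 12 genes in each direction past the threshold or, where none passed, the 5 of smallest unadjusted p in each direction, given as values; up to 4 members of smallest p for each list in the effect discussed; 15 key defence genes; and, at single ages, the 5 largest differences in each direction. For lists with fewer than 4 measured genes, the effect discussed was limited to genotype, and for senescence genes also to age; this limit was set after the alternatives had been seen.

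The labels give no replicate numbers, and the harvest age is a term of the model. As a check, deviations of the arrays from their genotype's mean were correlated across probe sets between the WT and mutant array of each age. The correlations were 0.605 at 5 weeks, 0.174 at 6 weeks and 0.436 at 7 weeks.

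The fits were tested on simulated data in which 200 of 22746 probe sets were changed by known amounts. For the genotype effect, 14%, 84%, 96% and 98% of probe sets changed by 1, 2, 3 and 4 on the log2 scale were recovered at an adjusted p under 0.05. For the age effect the shares were 2%, 76%, 92% and 96%. For the interaction they were 0% at each of these sizes, so that a count of 0 there says little. The simulated noise did not depend on expression level, and the many large changes ease the adjusted threshold. In the data, limma gave an unnamed probe set at 2.15 ± 0.11 for genotype an adjusted p of 0.244. It gave COR27 at 4.46 ± 0.30 for age one of 0.076. A count of 0 for genotype or age thus does not exclude changes of these sizes.

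Alternatives covered the normalization between arrays, a filter on the dimmest 40% of probe sets, the variance prior, the age and genotype terms, each array and each age left out, the threshold, and the list tests. Some were added after the data had been seen and are named as such with their values.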

Results

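The 6 arrays compared leaves of WT plants and of the mlo2 mlo6 mlo12 triple mutant aged 5, 6 or 7 weeks, with 1 array for each genotype and age. The series title places the work in a study of indolic metabolites in the antifungal defence of mlo2 plants. Array medians were 3.88, 3.81 and 3.81 for WT and 3.87, 3.82 and 3.82 for the mutant at 5, 6 and 7 weeks on the log2 scale. The first principal component held 49.1% of the variance and set both 5-week arrays (-42.5 for WT and -40.9 for the mutant) apart from the later ones. The 6-week WT array stood furthest from the rest, at 45.2 on that component, with a mean correlation with the other arrays of 0.970 against 0.975 to 0.982 for the others. Its poly-A spike-in controls averaged 5.16 on the log2 scale, close to the 5.20 of the 7-week WT array, and those of the other 4 arrays lay between 4.03 and 4.84. The 25S rRNA control probe set read 7.51, 4.08 and 3.87 in WT and 6.59, 5.39 and 5.70 in the mutant at 5, 6 and 7 weeks.

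The targeted genes MLO2, MLO6 and MLO12 had no probe set that the annotation gives to them alone, so the genotype labels were not checked through them. Of the 15 key defence genes only the plant defensin PDF1.2 could be named. It averaged -0.58 ± 0.68 (SE, log2, 3 arrays per genotype) in the mutant relative to WT, with differences of -0.17, -2.51 and 0.96 at the 3 ages. The lists of camalexin, penetration resistance, other MLO, floral transition and heat shock genes, and of flower, vascular and epidermal markers, had 0 measured members.

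The genotype comparison asked which transcripts differed between mutant and WT leaves over all 3 ages. No gene passed the adjusted threshold, and the genes of smallest unadjusted p are given as values. AT3G13610, a feruloyl-CoA hydroxylase of scopoletin synthesis, was 1.66 ± 0.14 (SE, log2) above WT, which is 3.16-fold, with differences of 1.48, 1.94 and 1.56 at 5, 6 and 7 weeks. AT1G43910 was 2.08 ± 0.24 above WT and AT3G48640 was 1.51 ± 0.16 above it. The subtilase SBT3.5 had an estimate of 1.18 ± 0.14 and the gibberellin receptor GID1B one of 0.95 ± 0.11. On the lower side were UGT72E1, a glycosyltransferase of the phenylpropanoid pathway, at -0.88 ± 0.10, AT3G03870 at -0.89 ± 0.11, the brassinosteroid-responsive RING-H2 gene BRH1 at -0.79 ± 0.10, AT1G12845 at -0.92 ± 0.13 and AT4G19390 at -0.76 ± 0.11. Each of these 10 genes kept its direction at all 3 ages, and their adjusted p-values in limma were 0.66 to 0.69. A choice by smallest p favours such agreement, since the error of the fit is the spread of the difference over ages. The probe set of smallest p is unnamed here. It was 2.15 ± 0.11 above WT, with an adjusted p of 0.244.

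**Figure D1:**
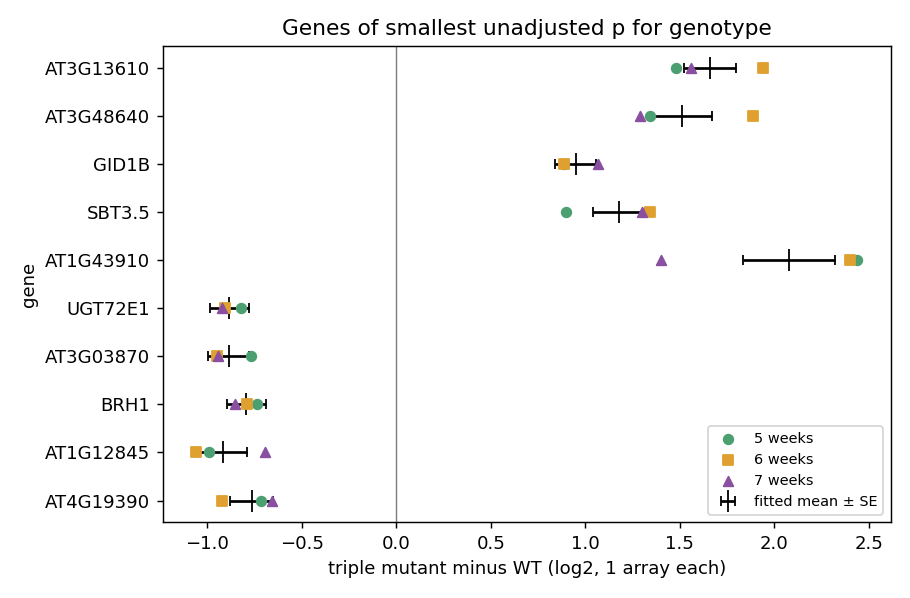
Mutant minus WT difference on the log2 scale (horizontal axis) for the 10 named genes of smallest unadjusted p in the genotype comparison (vertical axis). Coloured symbols are single-age differences of 1 array per genotype and black bars the fitted mean ± SE; AT1G43910 has the highest mean, 2.08, and AT1G12845 the lowest, -0.92.

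Members of the pattern-triggered immunity list, which holds receptors and signalling genes of the response to microbial patterns, were higher in the mutant as a group. All 6 measured members had estimates above 0, with a median of 0.25, and camera gave an adjusted p of 0.00437. The adjusted p was 0.357 with an estimated correlation. The examples of smallest p were the receptor EFR (0.40 ± 0.14), the receptor-associated kinase BIK1 (0.36 ± 0.13) and the ubiquitin ligases PUB23 (0.29 ± 0.21) and PUB22 (0.12 ± 0.13). The cold, drought and abscisic acid list was lower in the mutant: all 4 measured members were below 0, with a median of -0.62 and an adjusted p of 0.00523 (adjusted p = 0.357 with an estimated correlation). COR15A was at -0.64 ± 0.18, COR15B at -0.60 ± 0.19, COR47 at -0.70 ± 0.33 and LTI30 at -0.32 ± 0.42. The estimated correlation was 0.405 for the pattern-triggered list and 0.725 for the cold list, against the preset 0.01. Such estimates rest on 2 residual degrees of freedom and few genes, and that of the pattern-triggered list was -0.174 in the interaction. They neither show nor exclude that the members of a list depend on each other. The test with an estimated correlation also uses fewer degrees of freedom, so its higher adjusted p does not measure dependence alone. For neither list did a member pass over all probe sets, and 0 passed adjusted over the list alone. The nuclear photosynthesis list had 4 of 9 measured members above 0 and an adjusted p of 0.991; its median was -0.069 while its mean, 0.0038, and the test pointed upwards.

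Among the added lists, 28 named defence signalling genes were higher in the mutant as a group, 22 of them with estimates above 0 and a median of 0.24 (camera adjusted p = 4.32e-05; adjusted p = 0.532 with an estimated correlation). This list contains all 6 measured members of the pattern-triggered list. Adjusted over the list alone, 2 members passed: UGT76B1, which glucosylates salicylic acid and isoleucic acid, at 1.92 ± 0.24, and the subtilase SBT3.3 at 1.17 ± 0.14. UGT76B1 was above WT by 2.55, 1.76 and 1.46 at 5, 6 and 7 weeks. CML37, a calmodulin-like protein, was at 0.87 ± 0.24. Of the 22 members of the plastid gene-expression list, 21 were above 0, with a median of 0.36 (camera adjusted p = 1.7e-09, or 0.532 with an estimated correlation). Besides plastid-encoded genes for gene expression, the list holds accD, of fatty acid synthesis, and clpP, of a protease. The list's median difference was 0.255 at 5 weeks, 0.0747 at 6 weeks and 0.519 at 7 weeks. The 25S rRNA control, also without a poly-A tail, was higher in the mutant than in WT at 6 and 7 weeks and lower at 5 weeks.

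Another 13 of the lists written beforehand had 1 to 3 measured genes and were not tested as groups. For glucosinolates, UGT74B1 of the core pathway was at 0.057 ± 0.33, BCAT4 of the aliphatic branch at -0.64 ± 0.17 and UGT74C1 (AT2G31790) at -0.0605 ± 0.14. The tryptophan synthesis gene IGPS (AT2G04400) was at 0.41 ± 0.40. SAG101, which acts with EDS1 in immunity, was at 0.25 ± 0.26. The jasmonate genes THI2.1 and OPCL1 were at -0.27 ± 0.12 and -0.059 ± 0.19, and the second defensin, PDF1.2b, at -0.30 ± 0.68. The senescence genes WRKY53, WRKY6 and SAG29 were at 0.78 ± 0.48, 0.39 ± 0.27 and -0.19 ± 0.17. The detoxification genes UGT73B5 and GSTU25 were at 0.15 ± 0.19 and -0.021 ± 0.11, and the flavonoid genes UGT78D2, DFR and UGT75C1 (AT4G14090) at 0.36 ± 0.23, -0.14 ± 0.12 and -0.066 ± 0.12. The clock gene GI was at -0.46 ± 0.23, the mitotic kinase AUR1 at -0.081 ± 0.10, the guard cell regulator FAMA (FMA) at -0.065 ± 0.13 and the reference gene TIP41 (AT4G34270) at 0.022 ± 0.13. None of these 20 genes passed the threshold.

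In limma, 0 of 22746 probe sets passed an adjusted p of 0.05 for genotype, and 1482 had an unadjusted p under 0.05 (894 higher and 588 lower), where 1137.3 are expected by chance. The balance of directions turned with limma-trend (767 higher and 853 lower), without variance moderation (501 and 744) and without the 6-week arrays (1131 and 1173). With limma-trend 1 probe set passed. The number with an unadjusted p under 0.05 fell below the 1137.3 of chance without either 7-week array (684), with no age term (734) and with age as a number (1032). It stayed above in the other fits of all 22746 probe sets, and was highest, 2304, without the 6-week arrays. Both list calls were lost without either 7-week array (adjusted p = 0.0867 for the pattern-triggered list and 0.0802 for the cold list), that of the cold list also without either 5-week array (0.101), and that of the added defence list without either 7-week array (0.0993).

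The age comparison asked which transcripts differed between 7 and 5 weeks, averaged over the genotypes. The labels give no day or hour of harvest and no processing batch. Anything of this kind shared by the WT and mutant arrays of an age cannot be told apart from leaf age. Changes with age thus mean differences between the arrays of these ages, whatever their source. Plastid-encoded ribosomal protein genes had the lowest estimates among the named genes. rpl22 was at -3.79 ± 0.19 (SE, log2), 13.9-fold lower at 7 weeks, rps3 at -3.21 ± 0.19, rpl16 at -3.16 ± 0.24 and rps19 at -2.22 ± 0.14. AT1G51110 was at -1.90 ± 0.13. Higher at 7 weeks were the cold-regulated gene COR27 at 4.46 ± 0.30, which is 22-fold, AT5G55560 at 2.13 ± 0.15, AT2G27830 at 2.08 ± 0.15, AT5G16380 at 1.61 ± 0.14 and the methionine sulfoxide reductase MSRB9 at 1.59 ± 0.14. Each of these 10 genes had an adjusted p of 0.076 in limma and moved in the same direction in both genotypes, which a choice by smallest p favours.

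The added list of plastid genes for gene expression, which also holds accD and clpP, fell as a group with age. Of its 22 members 21 were below 0, with a median of -1.37, and 18 passed adjusted over the list alone (camera adjusted p = 8.72e-19; adjusted p = 0.324 with an estimated correlation; adjusted p = 0.0328 in fry). The medians were -1.40 in WT and -1.38 in the mutant. The 25S rRNA control moved in the same direction, by -3.64 in WT and -0.89 in the mutant. Other controls differed with age too. The poly-A spike-ins averaged 4.03 at 5 weeks and 5.20 at 7 weeks in WT, and 4.21 and 4.84 in the mutant. The 3 prime minus 5 prime difference of actin was 0.98 and 0.78 in WT and 0.96 and 0.79 in the mutant. That of ubiquitin was 1.14 and 1.22 in WT and 1.15 and 1.26 in the mutant, and that of GAPDH 0.69 and 0.92 in WT and 0.89 and 0.76 in the mutant. The plastid-encoded photosynthesis genes fell by less, with a median of -0.43 and 35 of 37 members below 0 (adjusted p = 6.69e-10; adjusted p = 0.374 with an estimated correlation). Among them were cemA at -1.53 ± 0.13 and psbZ at -1.29 ± 0.14.

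**Figure D2:**
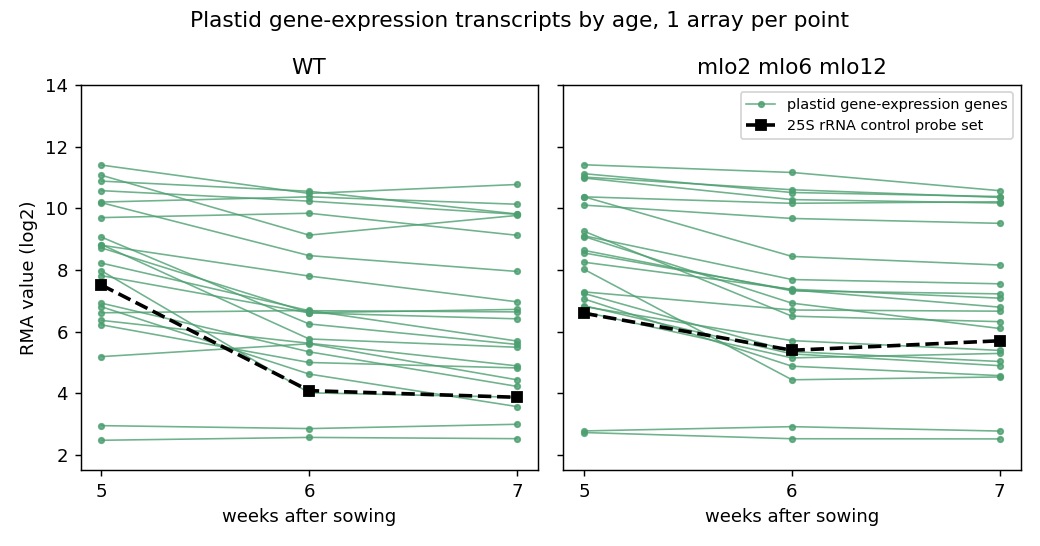
Deposited log2 values (vertical axis) of the 22 members of the plastid gene-expression list (green lines) and of the 25S rRNA control probe set (black dashed line). The horizontal axis is plant age of 5, 6 or 7 weeks, with WT on the left and the triple mutant on the right and 1 array per point. The list also holds accD and clpP, which are not genes for gene expression. The list's median difference between 7 and 5 weeks was -1.40 in WT and -1.38 in the mutant.

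The nuclear photosynthesis list also fell as a group, with 9 of 9 measured members below 0 and a median of -0.29 (camera adjusted p = 0.00209; adjusted p = 0.267 with an estimated correlation). The Calvin cycle enzyme SBPASE was at -1.05 ± 0.23 and Rubisco activase RCA at -0.58 ± 0.14; these 2 passed adjusted over the list alone. PRK was at -0.45 ± 0.15 and PSAN at -0.30 ± 0.14. The list's median was -0.15 in WT and -0.38 in the mutant, with 9 of 9 lower in both. The cold, drought and abscisic acid list rose, with 4 of 4 above 0 and a median of 1.08 (adjusted p = 0.00209; adjusted p = 0.267 with an estimated correlation). COR15A, at 1.54 ± 0.22, and COR15B, at 1.11 ± 0.23, passed adjusted over the list alone, while COR47 was at 1.04 ± 0.41 and LTI30 at 0.40 ± 0.52. The median was 1.15 in WT and 0.999 in the mutant, with 4 of 4 higher in both. The pattern-triggered list rose with 6 of 6 above 0 and a median of 0.42 (adjusted p = 0.00962; adjusted p = 0.267 with an estimated correlation). Its median was 0.14 in WT and 0.68 in the mutant, and 3 of 6 members were higher in both. Its member BIK1, at 0.80 ± 0.15, passed adjusted over the list alone. PUB23 was at 0.63 ± 0.25, PUB24 at 0.79 ± 0.35 and EFR at 0.21 ± 0.17. The added defence list rose too, with 24 of 28 above 0 (median 0.65, adjusted p = 5.99e-05; adjusted p = 0.482 with an estimated correlation). Its median was 0.31 in WT and 0.87 in the mutant, and 16 of 28 members were higher in both. GRX480, a glutaredoxin induced by salicylic acid, was at 2.03 ± 0.44 and WRKY47 at 1.14 ± 0.21. The senescence genes WRKY6, WRKY53 and SAG29 were at 1.04 ± 0.34, 1.08 ± 0.59 and 0.14 ± 0.21.

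In limma, 0 probe sets passed an adjusted p of 0.05 for age, and 3691 had an unadjusted p under 0.05 (1795 higher and 1896 lower). The balance of directions turned with the arrays shifted to the same median (2224 higher and 1542 lower), after a second quantile normalization (1860 and 1856), with age as a number (1393 and 1390) and without the 7-week WT array (1107 and 1069). At an adjusted p of 0.10 the count was 524, with limma-trend 258, with the dim probe sets left out 172, and without the 6-week arrays 1755. The 6-week arrays do not enter the 7 minus 5 week estimate, only its error. The median SE was 0.163 with them and 0.134 without them, with fewer residual degrees of freedom. The pattern-triggered call was lost without the 5-week or the 7-week mutant array (adjusted p = 0.195 and 0.12).

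The interaction asked whether the difference between mutant and WT changed from 5 to 7 weeks. AGL19, a MADS-box gene that promotes flowering, had the smallest p: its difference went from -0.25 at 5 weeks to 1.84 at 7 weeks, a change of 2.09 ± 0.29 (SE, log2). Changes upwards were also estimated for AT1G26390, a berberine bridge enzyme-like gene (1.92 ± 0.29), AT4G18250 (1.87 ± 0.32), AT1G52800 (1.74 ± 0.33) and the auxin-conjugating enzyme GH3.3 (1.5 ± 0.30). Changes downwards were estimated for HYH, a bZIP factor of light signalling (-1.75 ± 0.28), AT3G21670 (-2.39 ± 0.44), AT5G47610 (-1.57 ± 0.30), AT5G62130 (-1.54 ± 0.30) and AT1G69523 (-1.41 ± 0.29). The adjusted p in limma was 1 for each of these 10 genes.

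The pattern-triggered list shifted further above WT with age. All 6 members had positive changes, with a median of 0.35 (camera adjusted p = 0.00385; adjusted p = 0.243 with an estimated correlation; adjusted p = 0.035 in fry). EFR was at 0.46 ± 0.28, PUB23 at 0.66 ± 0.45, PUB22 at 0.34 ± 0.31 and WRKY22 at 0.33 ± 0.35. The added defence list shifted the same way, with 21 of 28 above 0 and a median of 0.35 (adjusted p = 0.00025; adjusted p = 0.823 with an estimated correlation). WRKY53, a regulator of senescence and defence, changed by an estimated 2.42 ± 0.53, the osmotin-like gene OSM34 by 2.2 ± 0.91, WRKY6 by 1.01 ± 0.53 and UGT76B1 by -1.09 ± 0.53. The cold and nuclear photosynthesis lists each had an adjusted p of 0.31.

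In limma, 0 probe sets passed an adjusted p of 0.05 for the interaction and 233 had an unadjusted p under 0.05, fewer than the 1137.3 expected by chance. The median SE was 0.40. With age as a factor, which takes changes at 6 weeks common to both genotypes out of the error, it was 0.38, 0 probe sets passed and 256 had an unadjusted p under 0.05. With limma-trend 0 passed. With 1 array left out 0 passed too, but the count with an unadjusted p under 0.05 depended on the array. It was 3180 without the 5-week WT array and 3907 without the 7-week WT array, above chance. Without any 1 of the other arrays it was 53 to 772, below chance. Without a 5-week or 7-week array, the change of its genotype is extrapolated from its 6-week array and 1 other array. Such fits cannot tell the part of the left-out array from that of the 6-week array. The call of the pattern-triggered list was lost with the dim probe sets left out (adjusted p = 0.113) and without any 1 of the 5-week and 7-week arrays (0.163 to 0.302), and that of the added defence list without the 5-week mutant array (0.431) or the 7-week WT array (0.366, with the direction turned).

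At single ages, 297 probe sets differed at least 2-fold between mutant and WT at 5 weeks (199 higher and 98 lower), 1122 at 6 weeks (674 and 448) and 420 at 7 weeks (325 and 95), with no replicate of any array. At 5 weeks the named genes highest relative to WT were UGT76B1 (2.55), AT1G43910 (2.44), AT2G44240 (2.29), AT1G65870 (2.25) and TBL26 (2.19), and the lowest AT4G16260 (-1.66), AT2G05540 (-1.56), AT3G23550 (-1.49), IQD31 (-1.34) and AT4G08310 (-1.34). At 6 weeks, where the WT array stood apart, the highest were AT1G43910 (2.40), AT5G17760 (2.09), VPS60.1 (2.08), AT1G16670 (2.06) and the photosystem I core gene psaA (2.04), and the lowest the peroxidase AT2G37130 (-2.67), PDF1.2 (-2.51), AT4G21870 (-2.41), AT4G12500 (-2.2) and AT1G64380 (-2.19). At 7 weeks the highest were AT3G28510 (2.47), AT4G12500 (2.47), ARL (2.33), OSM34 (2.24) and AT5G03610 (2.19). The lowest were AT3G28220 (-4.88), the drought-inducible linker histone HIS1-3 (-3.10), AT1G52000 (-2.68) and the thionin genes AT1G66100 (-2.48) and THI2.2 (-2.2).

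The median difference of the added defence list was 0.077 at 5 weeks, 0.056 at 6 weeks and 0.60 at 7 weeks, at percentiles 93.0, 80.0 and 100 of random lists. That of the pattern-triggered list was 0.099, 0.31 and 0.45 (percentiles 85.3, 97.9 and 99.9). The cold list lay at -0.89 and -1.04 at 5 and 7 weeks, each at percentile 0, and at 0.059 at 6 weeks (percentile 59.7). The nuclear photosynthesis list stayed between -0.023 and -0.080 (percentiles 20.9 to 55.5).

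**Figure D3:**
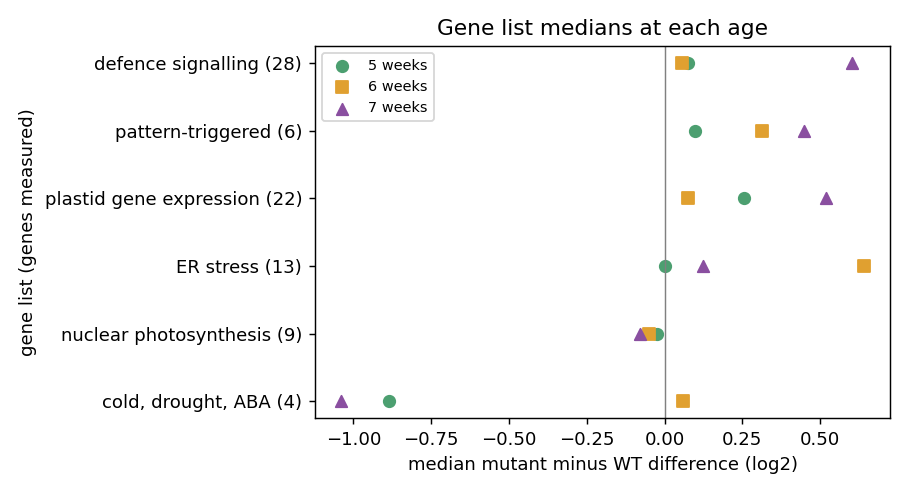
Median difference of the triple mutant minus WT on the log2 scale (horizontal axis) for 6 gene lists with their numbers of measured genes (vertical axis), at 5 weeks (circles), 6 weeks (squares) and 7 weeks (triangles), from 1 array per genotype and age. The defence signalling list lies at 0.077, 0.056 and 0.60 and the cold, drought and abscisic acid list at -0.89, 0.059 and -1.04.

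Whether the genotype difference ran along the age change was asked by setting the 2 estimates against each other. No probe set passed the adjusted threshold in both. Across the 22746 probe sets, which are not independent, the estimates correlated with r = -0.213. Among probe sets with an unadjusted p under 0.05 in both, 255 were higher in the mutant and lower with age, 214 lower in the mutant and higher with age, 128 higher in both and 48 lower in both. Both p-values use the same residual variance of a probe set, so these counts have no reference from independent lists. The correlation was -0.0393 without the 6-week arrays and 0.109 without the 5-week WT array, and it was -0.425 without the 7-week WT array, -0.452 without the 5-week mutant array and -0.0991 without the 7-week mutant array.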

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

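The spike-in, RNA quality and plastid list tests below were chosen after the results they bear on had been seen, except for leaving out single arrays, leaving out dim probe sets, the comparison of the 6-week WT array with the age change, and the counts over other splits of the arrays. The added lists, and the alternatives without the 6-week arrays, were also chosen after the data had been seen.

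The interaction test picked out 6 lists whose mutant minus WT difference changed between 5 and 7 weeks. The median change was 0.352 on the log2 scale for the pattern-triggered list and 0.352 for the added defence list. Among the other added lists it was 0.202 for autophagy genes, which are ATG8 family members and ATG3. It was -0.236 for SWEET sugar transporters, 0.066 for CYP71B cytochrome P450 genes and -0.108 for plastid-encoded photosynthesis genes. The estimated-correlation version of the test gave adjusted p-values of 0.243 for the first and 0.823 to 0.836 for the added lists. The estimated correlation was 0.74 for SWEET genes and between -0.174 and 0.278 for the other lists.

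For the defence list, dim probe sets as the source are argued against, since the adjusted p was 3.04e-06 without them. Single arrays do matter. The highest adjusted p with 1 array left out was 0.431, without the 5-week mutant array, and the direction turned without the 7-week WT array. With 1 array per genotype and age, a difference between individual leaf samples may therefore be the source, and a defence difference that grows with age in the mutant stays open as an untested biological explanation.

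The fall of the plastid gene-expression list between 5 and 7 weeks was not set by 1 array at the preset correlation, as the highest adjusted p with 1 array left out was 1.11e-14; with an estimated correlation and all arrays the adjusted p was 0.324. A uniform loss of plastid or untailed RNA would lower both plastid lists alike, but the photosynthesis list had the smaller mean fall. The difference of the list means was -0.89 (two-sided permutation p over genes = 0.00013). The permutation treats genes as independent, and the lowest members, rpl14, rpl16, rps3 and rpl22 (-2.86 to -3.79), are neighbouring loci. Genes of 1 plastid transcription unit are not independent, so the test cannot decide against such a loss. Less labelling of RNA without poly-A tails at the later ages may still contribute. The 25S rRNA control fell in both genotypes, which goes with it, while the mitochondrially encoded list had a mean change of 0.387 ± 0.0999 (SE over 15 genes), which goes against it, so it cannot be told apart from a change in plastid transcripts with leaf age. The spike-ins and the actin control also differed between 5 and 7 weeks in both genotypes, and a part of RNA quality or input in the fall was not tested. Harvest conditions or a batch shared by both genotypes at an age cannot be told apart from leaf age either.

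The 6-week WT array differed from the 6-week mutant array in 1122 probe sets. A high share of spike-in RNA alone is argued against, because the 7-week WT array had as much (difference -0.0413 ± 0.0503, SE over 24 probe sets) without standing apart. Degraded RNA cannot be told apart from other sources: the difference between 3 prime and 5 prime probe sets was highest in this array for 2 of the 3 control transcripts, actin and GAPDH, and lowest for ubiquitin. Material further along the age change is possible but undecided. The 6-week WT minus mutant difference correlated with the mutant's 7 minus 5 week difference at r = 0.178 across probe sets. The 5-week WT minus mutant difference gave r = 0.0568 with the mutant's 7 minus 6 week difference. That of 7 weeks gave r = -0.124 with the mutant's 6 minus 5 week difference. These 2 values use other age intervals, so they are no direct reference for the first. The opposite direction of the genotype and age estimates may come from the 6-week arrays, since r was -0.0393 without them. The values without the 5-week WT array (0.109) or the 7-week mutant array (-0.0991) cannot decide this. Leaving out 1 array of those ages puts part of the genotype estimate into the age estimate, which moves r upwards in both fits.

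With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For genotype, splits that part the arrays of only 1 age give the same fit in pairs, so there are fewer distinct fits than splits. Only the splits that part the arrays of every age repeat the kind of comparison made by the real one. The real split gave 1482 probe sets with an unadjusted p under 0.05 for genotype, 4 splits, the real one included, gave at least as many, and the highest other gave 3839; those 3839 came from the splits that part only the 6-week arrays within an age, which points to the difference between the WT and mutant arrays of 6 weeks. Among the splits that part the arrays of every age, the highest other gave 1503. For gene lists past the threshold the real split gave 9 for genotype and the other splits 3 to 7, so that 1 split, the real one, was as large. Other splits that part the arrays of every age gave 4, 6 and 7. Wrong groupings thus also gave several list calls, and with 10 splits the higher count of the real one cannot be told from chance. For the interaction the real split gave 6 and the highest other 9, and 5 splits, the real one included, were at least as large.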

How the results depend on the processing

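The alternatives that left out both 6-week arrays for gene lists, all those of the added lists, the single adjustment over all lists, age as a factor in the interaction, and those of the correlation below were chosen after the data had been seen. Of 2233 alternative values of named genes, 2050 kept their direction and their side of the threshold, 131 kept their direction and passed it, and 52 changed sign. The alternatives of the variance prior leave the estimate as it is, so their values could not change sign. The cause was not tested for any change below unless one is named. Leaving out either array of an age gives the same genotype estimate as leaving out both, because the remaining array is absorbed by its own age term. Such repeats are counted separately above. The interaction without an age, and the age effect without 5 or 7 weeks, could not be fitted. The number of arrays and the compression of dim probe sets limit all results.

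The genotype count of 0 became 1 with limma-trend and stayed 0 under the other alternatives. The age count of 0 became 172 with dim probe sets left out, where the smallest adjusted p was 0.00945 against 0.076 before, 258 with limma-trend, 9 with no genotype term, 524 at an adjusted p of 0.10 and 1755 without the 6-week arrays. With 1 array left out it ranged from 0 to 1755. The interaction count was 0 throughout, also with age as a factor, which was chosen after seeing the data and left 256 probe sets with an unadjusted p under 0.05. With 1 array left out that unadjusted count ranged from 53 to 3907, against 233 with all arrays. At an absolute log2 difference of at least 1.5 the single-age counts fell to 58, 200 and 128, as a stricter limit must; the dim filter and a second quantile normalization, the latter chosen after seeing the data, left them within 1.5 times.

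For genotype, the 2 lists past the threshold became 0 with an estimated correlation and 0 in fry, and 0 to 2 with 1 array left out. The cold list had adjusted p = 0.357 with an estimated correlation, 0.33 in fry and 5.97e-07 to 0.101 with 1 array left out; the pattern-triggered list 0.357, 0.33 and 0.00196 to 0.0867. The photosynthesis list, not past the threshold, turned downwards in fry (0.755), with dim probe sets left out (0.806) and without the 6-week arrays (0.465); the range with 1 array left out was 0.381 to 0.918. The 7 added lists became 0 with an estimated correlation and 0 in fry. For age, the 3 lists became 0 in both, with adjusted p-values of 0.267 with an estimated correlation and 0.133 in fry for each; the pattern-triggered list ranged over 0.00149 to 0.195 with 1 array left out. The 8 added lists became 0 and 1. For the interaction, the pattern-triggered call became 0 with an estimated correlation (0.243) and with dim probe sets left out (0.113), and 0 to 1 lists passed with 1 array left out, where its adjusted p ranged over 0.00355 to 0.302. With 1 array left out the cold list ranged over 0.000345 to 0.718, past the threshold downwards without the 5-week WT array and upwards without the 7-week WT array, and the photosynthesis list over 0.200 to 0.718. With age as a factor the pattern-triggered list had adjusted p = 0.0101 and the cold and photosynthesis lists 0.311 each, and the number of added lists became 6. The 5 added lists became 0 with an estimated correlation and 0 in fry, and 1 to 5 with 1 array left out. Directions turned in some of these for defence (2.3e-05 to 0.431), autophagy (0.000767 to 0.984), plastid photosynthesis (4.54e-06 to 0.984), CYP71B (0.0274 to 0.889) and SWEET genes (0.00158 to 0.431). One adjustment over all lists, added after seeing the data, left every count within 1.5 times.

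Of 146 results of named genes, 21 changed sign under an alternative, and their estimates ranged in size from GSTU25 (-0.021, genotype) to SWEET2 (-1.35, interaction). Without the 6-week arrays the genotype estimates were UGT74B1 at -0.28, AT2G04400 at -0.11, AT2G31790 at 0.086, PDF1.2 at 0.39, PDF1.2b at 0.57, SAG29 at 0.021, FMA at 0.014, AT4G34270 at -0.088. Without the 5-week arrays the genotype estimates were LTI30 at 0.077, OPCL1 at 0.11. Without the 7-week arrays the genotype estimates were UGT74B1 at -0.077, OPCL1 at 0.0082, AT4G14090 at 0.024. After a second quantile normalization the genotype estimates were UGT74B1 at -0.0062, GSTU25 at 0.012, AT4G34270 at -0.028. With 1 array left out, genotype estimates ranged from -0.93 to 0.077 for LTI30, -0.28 to 0.52 for UGT74B1, -0.11 to 0.92 for AT2G04400, -0.16 to 0.086 for AT2G31790, -0.30 to 0.11 for OPCL1, -1.34 to 0.39 for PDF1.2, -1.2 to 0.57 for PDF1.2b, -0.30 to 0.021 for SAG29, -0.14 to 0.024 for AT4G14090, -0.17 to 0.014 for FMA, -0.088 to 0.14 for AT4G34270. With 1 array left out, age estimates ranged from -0.19 to 0.99 for LTI30, -0.026 to 0.30 for SAG29. With 1 array left out, interaction estimates ranged from -0.13 to 1.45 for PUB23, -0.11 to 0.78 for WRKY22, -0.17 to 2.46 for ATG8G, -0.53 to 1.33 for APG8A, -3.02 to 0.31 for SWEET2, -1.03 to 0.0503 for SWEET16, -2.4 to 0.22 for psbB.

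The correlation of genotype and age estimates, -0.213, ranged from -0.452 to 0.109 with 1 array left out and was -0.0393 without the 6-week arrays, all chosen after seeing the data; leaving out 1 array unbalances the design.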

Other observations

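Further added lists, formed after array-level values had been seen, were tested for each effect with camera. Genes of the endoplasmic reticulum stress response were higher in the mutant, with 12 of 13 above 0 and a median of 0.23 (adjusted p = 0.000356; adjusted p = 0.817 with an estimated correlation). The co-chaperones ATERDJ2B and ATERDJ3B were at 0.45 ± 0.14 and 0.79 ± 0.36 (SE, log2) and the transcription factor BZIP60 at 0.23 ± 0.12. The estimated correlation of its members was 0.779. The call was lost without either 6-week array (0.656). The list's median difference was 0.64 at 6 weeks against 0.0020 and 0.12 at 5 and 7 weeks. Plastid-encoded NADH dehydrogenase-like subunits (9 of 10 above 0, median 0.39, adjusted p = 3.81e-05) and photosynthesis genes (27 of 37, median 0.19, adjusted p = 8.35e-05) were also higher in the mutant, with adjusted p = 0.532 for each with an estimated correlation. Lower in the mutant were late embryogenesis and dehydration genes (12 of 12 below 0, median -0.24, adjusted p = 0.00465), which include the measured cold list, and mitochondrially encoded genes (12 of 15 below 0, median -0.22, adjusted p = 0.00758), again with adjusted p = 0.532 with an estimated correlation. COR27 was at -1.10 ± 0.24 and nad5 at -0.52 ± 0.15. The late embryogenesis call was lost without either 5-week array (0.0559), and the mitochondrial call without either 5-week array (0.0792) or either 7-week array (0.0971).

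For changes between 5 and 7 weeks, leaf age again cannot be told apart from the harvest. Averaged over the genotypes, autophagy genes rose as a group (9 of 10 above 0, median 0.55, adjusted p = 0.00607, or 0.482 with an estimated correlation). All members of this list except ATG3 belong to the ATG8 family, so it does not sample autophagy genes broadly. The median was 0.17 in WT and 0.76 in the mutant, and 5 of 10 were higher in both. Among them were ATG8D at 2.05 ± 0.19 and ATG8C at 0.87 ± 0.14, both past the threshold adjusted over the list alone. Mitochondrially encoded genes rose (13 of 15, median 0.34, adjusted p = 0.000293), as did late embryogenesis and dehydration genes (11 of 12, median 0.42, adjusted p = 0.000293). The NADH dehydrogenase-like subunits fell (9 of 10 below 0, median -0.82, adjusted p = 0.000293) and glutathione transferases fell (11 of 14 below 0, median -0.13, adjusted p = 0.0413), with GSTU20 at -0.91 ± 0.15. With an estimated correlation the adjusted p of these 5 lists was 0.374 to 0.482. The autophagy call was lost without the 5-week or the 7-week mutant array (0.341 and 0.114). That of the glutathione transferases was lost without the 5-week or the 7-week mutant array (0.354 and 0.242), without either 6-week array (0.0609) and without dim probe sets (0.194). In the interaction, autophagy (10 of 10 above 0, adjusted p = 0.0178), CYP71B (10 of 18 above 0, adjusted p = 0.0242), SWEET (11 of 14 below 0, adjusted p = 0.0242) and plastid photosynthesis genes (23 of 37 below 0, adjusted p = 0.0242) passed, with adjusted p-values of 0.823 for autophagy and CYP71B and 0.836 for SWEET and plastid photosynthesis genes with an estimated correlation. Each of these 4 calls was lost or turned in direction without the 5-week mutant array (0.984, 0.431, 0.431 and 0.984). Without the 7-week WT array autophagy (0.575) and plastid photosynthesis genes (0.0312) turned, and without the 5-week WT array CYP71B (0.889) and SWEET genes (0.135) did. Without the 7-week mutant array the calls of CYP71B (0.226) and SWEET genes (0.19) were lost, and without the 6-week WT array that of plastid photosynthesis genes (0.132). Fits without a 5-week or 7-week array extrapolate from the 6-week array of that genotype, so they do not single out the left-out array. The added lists that did not pass had adjusted p-values of 0.51 to 0.922 for genotype, 0.211 to 0.707 for age and 0.139 to 0.952 for the interaction.

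Of the 64 control probe sets of the array, 3 read higher in all 3 mutant arrays than in all 3 WT arrays and 0 lower, where chance gives 5% in each direction. They were 2 of the GAPDH probe sets, 1 at the 3 prime and 1 at the 5 prime end, and a ubiquitin probe set, with mean differences of 0.30, 0.37 and 0.29.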
